A study of Mus musculus with 6 samples.

How the data were processed

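RNA from RiboTag immunoprecipitates of the spinal cord injury site of LysM-Cre chimeras was made into libraries with the ScriptSeq v2 kit, per the labels' protocols, at 3 and 7 days after injury with 3 libraries each. Per the submitters' processing notes, TopHat2 2.0.12, Cufflinks 2.2 and Cuffdiff 2.2.1 and the mouse build mm10 were used; the notes give no role or order. The authors deposited an unfiltered and a filtered table of genes. Per the file headers, both hold an FPKM value for each gene and library (fragments scaled to transcript length and to mapped fragments) and the authors' mean FPKM at each time. How the libraries were scaled to each other is not stated. The deposited log2 fold change lay within 0.01 of the log2 ratio of the authors' 7-day mean over their 3-day mean in 12768 of the 12772 tested rows with both means above 0, and in 300 of 862 such rows among those set aside. A p-value and a q-value per gene from the authors' own test are deposited beside it. How the filtered table was filtered is not stated. Library values of the 10072 symbols on 1 row of each table are identical in both.

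The unfiltered table, with 13960 rows for 13940 symbols, was analysed. Of these, 918 rows were set aside before any test: 45 with a test status other than OK, 838 whose 3 library values miss the authors' mean by over 1%, 14 listed at 0 in a library beside 100 FPKM or more in another, and 32 of symbols on more than 1 row; some rows meet more than 1 of these. The 13042 other genes were tested without a filter on low values. Symbols are as the authors give them, 12873 of them found in the GENCODE M21 annotation. Coordinates are mm10 positions as the authors' table gives them, and whether its starts count from 0 or 1 was not stated.

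FPKM values were transformed as log2(FPKM + 1) and tested with limma 3.58.1 with a mean-dependent prior variance (R 4.3.3), 7 days minus 3 days, two-sided, with Benjamini-Hochberg adjustment over the 13042 genes. A gene was called at an adjusted p of 0.05 or less. Reported log2 changes are the fitted differences of log2(FPKM + 1), with their SE; means and SD are of FPKM. An exact test of 3 against 3 libraries cannot go below p = 0.1, so the calls rest on the variance that limma shares across genes. FPKM cannot be turned back into counts, so no counting interval is given, and the number of reads behind each gene is unknown. A relative depth was read from the smallest step between FPKM values of genes with few reads. It is a depth only if each library was scaled to its own mapped fragments, and the scaling is not stated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

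Before the data were examined, 21 gene lists, 14 cell type marker lists and the tests were fixed. A later list or test is named as such where it is reported. Members called higher and lower were tested against all other tested genes with a one-sided Fisher exact test, adjusted over the 35 lists and both directions. Direction was tested with limma's camera (preset correlation 0.01), adjusted over the 35 lists, and again with the correlation estimated from the libraries, and with fry. The camera calls, 9 lists higher and 12 lower, all ended with the estimated correlation. The adjustment then gave the same 0.346 to lists whose unadjusted camera p ran from 0.0227 (inflammatory monocyte) to 0.208 (oligodendrocyte markers). A value of 0.346 is therefore not a measure of how strongly the members of a list are correlated. Fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, gave an adjusted p of 0.05 or less to each of these 21 lists. The list medians were set beside 10000 random lists of the same size drawn within 20 bins of mean expression. Counts adjusted over the list alone use Benjamini-Hochberg over the members of a list. The lists were not chosen on these samples, but the series title, which names lipid catabolism, was known.

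The genes named in the text follow a rule fixed beforehand. It takes the 8 genes with the largest log2 change in each direction among those called with a larger group mean of 10 FPKM or more, a smaller mean above 0 and times that do not overlap, leaving out predicted genes, clones, pseudogenes and small RNAs. It adds up to 4 called members of each list with the largest changes and a larger mean of 1 FPKM or more, and Cd36, Abca1, Apoe, Trem2, Pparg, Nr1h3, Lyz2 and Rpl22 always. This gave 133 genes with values, of which 29 lost their call under some alternative. All but 4 of the 133 are printed, with their lost calls; the 4, of which 2 lost their call, were left out for a reason unrelated to their values. Genes with near-identical copies (globins, Ccl chemokines, H2 genes, Chi3l3) are given as uncertain, since the counting may split their reads.

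The scripts were tested on simulated data of 13042 genes with the spread of these libraries. In them 200 genes were changed, drawn from the 11073 with a mean of 1 FPKM or more. The changes were 2-fold or 4-fold in FPKM + 1, which is more than that in FPKM where values are low. For 7 days against 3 days, 58% of the genes changed by 2-fold and 94% of those changed by 4-fold were called with the right sign. There were 5 false calls (3.19% of the calls), and 0 calls were made where nothing was changed. Recovery of genes under 1 FPKM was not simulated. The simulated noise was independent between genes and no library stood apart. These rates may therefore not hold for the calls made here, where many more genes were called. The alternatives were other thresholds on p, fold and FPKM, the authors' filtered table, a pseudocount of 0.1, centring on the median gene, the replicate number as a block, and leaving out each library. Added after seeing the data were quantile normalization, the rows with unmatched means, the authors' q-values as the calls and the estimated correlation. The list results without each library, the list medians and camera calls of single lists in the authors' filtered table, and the refits of named genes were also added then. Further added were 7 gene lists. The 156 symbols in the filtered table alone were not used in the comparison.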

Results

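The libraries were made from precipitates meant to hold ribosome-bound RNA of macrophages at a spinal cord injury in mice; they also held RNA with markers of other cells, given below. LysM-Cre, which is active in macrophages and other myeloid cells, switched on an epitope tag on the ribosomal protein Rpl22 (the RiboTag method), and tagged ribosomes were precipitated from the injury site of chimeras after a contusion at T8. There were 3 libraries at 3 days and 3 at 7 days after injury. No uninjured cord and no unprecipitated RNA is among the samples, so every value compares 7 days with 3 days. The labels do not say whether each library came from its own animal, and the p-values measure the spread between these libraries.

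Genes at 1 FPKM or more numbered 11147, 11675 and 11258 in the 3-day libraries and 10248, 10280 and 10402 in the 7-day libraries, of 13042 tested. The total number of reads is unknown, because the values are deposited as FPKM. The depth relative to 3-day replicate 1, read from the step between the lowest FPKM values, was 0.939 in 3-day replicate 2 and 0.758 in 3-day replicate 3. The 7-day depths of 0.812, 0.819 and 0.887 rest on an inferred step. All of these values would differ from the true relative depth if the libraries were scaled by more than their own mapped fragments. The 50 most abundant tested genes held 27.6% of the summed FPKM of tested genes in 3-day replicate 3 and between 14.6% and 19.7% in the other 5 libraries. Very abundant genes that were set aside, such as Ctss and Apoe, are not part of these shares. Across genes, which are not independent replicates, log2 values of libraries correlated with r from 0.964 to 0.971 within 3 days, from 0.978 to 0.983 within 7 days and from 0.913 to 0.938 between the times.

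The comparison of 7 days with 3 days asked how the profile of the precipitates changes over the days after injury; the series title names lipid catabolism as the point of interest. At 7 days, 20 of 27 lysosome genes and 11 of 16 lipid droplet and lipolysis genes were higher (22 and 11 adjusted over the list alone). In turn, 19 of 20 interferon response genes and 15 of 25 chemokines and receptors were lower (19 and 16 adjusted over the list alone). Of the 35 fixed lists, camera called 9 higher and 12 lower at 7 days, and 0 of them with an estimated correlation (adjusted p of 0.346 or more). The 10 macrophage markers had a median log2 change of 0.57 in the same libraries. Of all genes tested, 2453 were higher and 2645 were lower at a limma adjusted p of 0.05 or less, and 7944 were not called. By the one-sided Fisher exact test, 10 lists were enriched among the higher and 12 among the lower genes: complement in addition to the camera calls, and matrix proteases in place of pro-inflammatory activation. That test treats genes as independent, although members of a list move together (estimated correlation 0.41 for lysosome and 0.40 for interferon response genes). Its p-values are therefore too small where members are correlated. Quantile normalization left 5 lists higher by camera and 6 enriched among the higher genes. Of the called genes, 533 were higher by 2-fold or more in mean FPKM and 2020 were lower by 2-fold or more. The 3 libraries of 1 time all lay above the 3 of the other for 5066 of the 5098 called genes and for 55.4% of all tested genes, where chance gives 10%. The authors' deposited q-values of 0.05 or less held 4120 of these calls, none with the opposite sign, and left 978 called here alone and 893 by the authors alone. Without 7-day replicate 2 the counts were 1572 higher and 1697 lower. The balance of the calls turned with the scaling and with the genes tested: quantile normalization gave 2317 higher and 1809 lower, and centring on the median gene 2020 higher and 2977 lower. With genes at 5 FPKM or more it was 2385 higher and 1487 lower, and with the authors' filtered table it was 2388 and 1433. Genes that the authors' filtered table leaves out supplied 206 of the higher and 1279 of the lower calls.

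**Figure D1:**
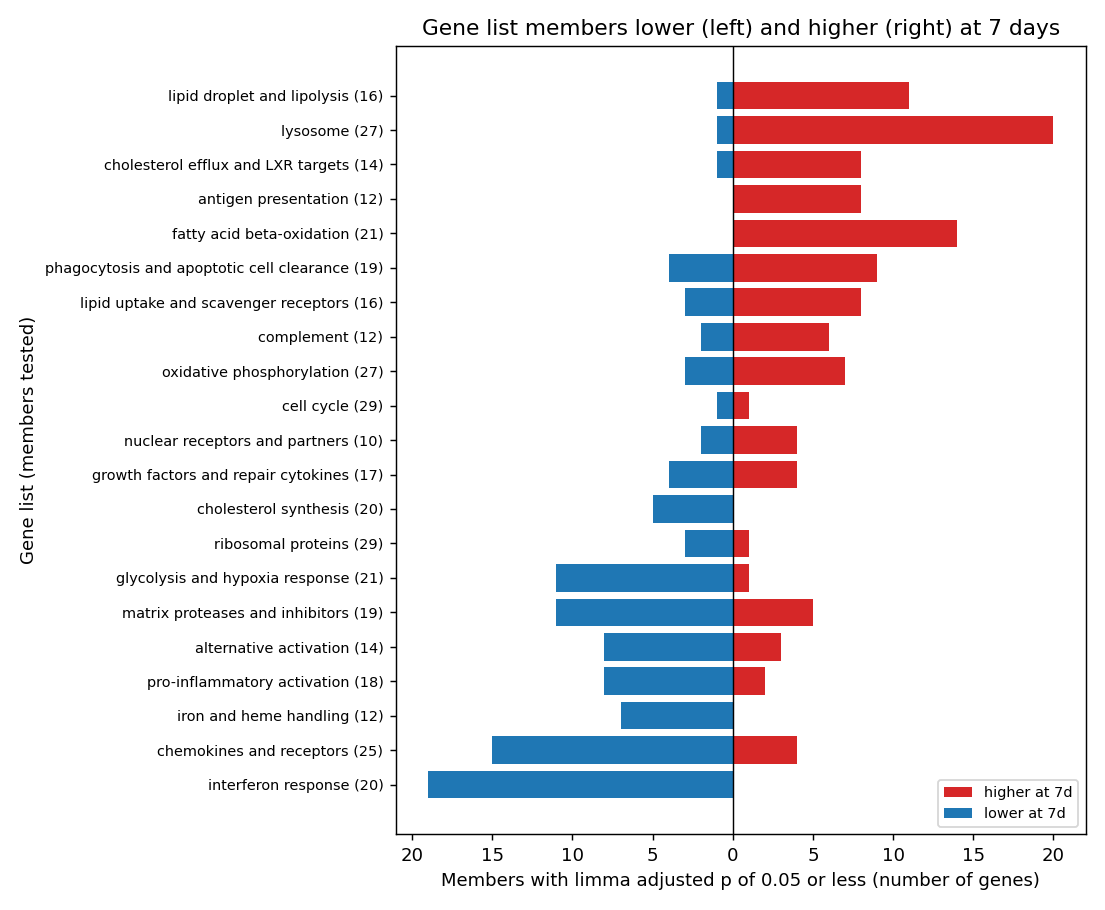
Number of tested members of each fixed gene list lower at 7 days (bars to the left of 0) and higher at 7 days (bars to the right) at a limma adjusted p of 0.05 or less, with the number tested in brackets after each name. Lists are ordered by their median log2 change, from lipid droplet and lipolysis (11 higher, 1 lower of 16) to interferon response (0 higher, 19 lower of 20).

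The median log2 change of each list was also placed among those of 10000 random lists of the same size and matched mean expression, as a description and not a test. Among the lists of functions, its percentile was 100 for lipid droplet, 100 for lysosome, 99.97 for efflux, 99.94 for antigen presentation and 99.78 for beta-oxidation genes. Lower places were 94.7 for phagocytosis, 89.53 for lipid uptake, 74.34 for complement, 54.25 for nuclear receptor, 39.67 for growth factor, 21.65 for cholesterol synthesis, 18.82 for cell cycle and 6.69 for oxidative phosphorylation genes. The lowest were 0.22 for alternative activation, 0.09 for pro-inflammatory, 0.08 for ribosomal protein, 0.04 for glycolysis, 0.01 for iron, 0 for interferon response, 0 for chemokine and 0 for matrix protease genes. Of the marker lists, the percentile was 99.98 for microglia, 97.74 for B cell, 94.51 for macrophage, 82.33 for T and NK cell, 51.26 for dendritic cell, 2.17 for Schwann cell and 0.9 for neutrophil markers. It was 0.17 for fibroblast and pericyte, 0.01 for astrocyte, 0 for inflammatory monocyte, 0 for oligodendrocyte, 0 for neuron, 0 for endothelial and 0 for erythroid markers. Lipid uptake, phagocytosis and macrophage lists, which camera called higher at the preset correlation and not at the estimated one (adjusted p = 0.346 each), thus lay below percentile 95.

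The genes with the largest increases included several of lipid handling and clearance. The scavenger receptor relative Cd5l measured 18.996 ± 2.56 FPKM at 3 days and 402 ± 55.5 FPKM at 7 days (SD, n = 3). Its log2 change was 4.33 ± 0.14 (SE; adjusted p = 2.72e-05; mm10 chromosome 3, 87327120 to 87371072). Lpl, the lipoprotein lipase that releases fatty acids from triglycerides, rose from 29.995 ± 3.96 to 363 ± 53.8 FPKM (log2 3.55 ± 0.15; chromosome 8, 68880554 to 68906996). The apolipoprotein gene Apoc1 rose from 10.998 ± 0.61965 to 107 ± 28.8 FPKM (log2 3.14 ± 0.18; chromosome 7, 19689481 to 19692668). Mmp12, the macrophage elastase, rose from 17.2 ± 4.81 to 181 ± 6.16 FPKM (log2 3.35 ± 0.18; chromosome 9, 7347381 to 7359013). Mfge8, which bridges dying cells to phagocytes, rose from 21.6 ± 4.18 to 187 ± 15.7 FPKM (log2 3.07 ± 0.15; chromosome 7, 79133368 to 79149078). Mcoln3, a mucolipin channel of endosomes and lysosomes, went from 5.37 ± 0.448 to 64.1 ± 4.13 FPKM (chromosome 3, 146117442 to 146141810). Cd28, a co-stimulatory receptor best known from T cells, went from 3.85 ± 0.702 to 40.6 ± 1.83 FPKM (chromosome 1, 60746360 to 60774008), and Pdzk1ip1 from 2.1875 ± 1.48 to 29.465 ± 5.84 FPKM (chromosome 4, 115089064 to 115093866).

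Among the genes with the largest decreases were genes of monocytes and of the interferon response, and markers of neurons and red cells. Slfn4, a myeloid gene induced by interferon, fell from 60.001 ± 14.2 to 2.37 ± 0.589 FPKM (log2 -4.17 ± 0.21; adjusted p = 7.58e-05; chromosome 11, 83175080 to 83190860). The monocyte marker Plac8 fell from 78.6 ± 10.8 to 5.27 ± 1.87 FPKM (log2 -3.70 ± 0.22; chromosome 5, 100553729 to 100572705). Cxcl10, an interferon-induced chemokine, fell from 34.6 ± 7.89 to 3.11 ± 0.646 FPKM (log2 -3.10 ± 0.19; chromosome 5, 92346641 to 92348866). The neuronal splicing factor Rbfox3, on the list of neuron markers, fell from 19.98 ± 6.47 to 0.844 ± 0.847 FPKM (chromosome 11, 118491029 to 118570094). The globin Hba-a2, on the erythroid list, fell from 135 ± 12.4 to 12.7 ± 3.0375 FPKM (chromosome 11, 32287359 to 32297338), and has a near-identical copy, so its value is uncertain. The matrix protein gene Tnc fell from 63.3 ± 30.9 to 5.63 ± 2.5485 FPKM (chromosome 4, 63961950 to 64047018) and Cdr1 from 14.96 ± 0.482 to 0.833 ± 0.192 FPKM (chromosome X, 61179096 to 61189446). Gli3, a factor of hedgehog signalling, went from 15.8 ± 6.47 to 0.684 ± 0.666 FPKM (chromosome 13, 15644215 to 15724679), with an authors' q-value of 0.103. Tnc and Gli3 were highest in 3-day replicate 2 (95.1 and 20.9 FPKM), the library with the highest neural marker sums, and Cdr1 was not. The authors' filtered table leaves out Tnc and Cdr1. Other genes given in this text that it leaves out include Apoc1, Cd163, Tyro3, Hbegf, Prtn3 and Thy1. It also leaves out the cell markers Mog, Mobp, Ugt8a, Cldn11, Slc1a2, Gfap, Stmn2, Tubb3, Tek, Esam, Cdh5, Pdgfra, Pdgfrb, Cdh19, Sox10, Hbb-b1 and Alas2.

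Several genes that take up or export lipid were higher at 7 days, and a few were lower. Cd36, a scavenger receptor for oxidised lipids and fatty acids, measured 595.5 ± 49.4 FPKM at 3 days and 2121 ± 77.2 FPKM at 7 days (SD, n = 3). This was a 3.56-fold rise (log2 1.83 ± 0.15, SE; adjusted p = 3.83e-04; chromosome 5, 17781680 to 17849815). Abca1, which loads cholesterol onto apolipoproteins, rose from 219 ± 25.8 to 556 ± 42.97 FPKM (log2 1.34 ± 0.13; adjusted p = 6.87e-04; chromosome 4, 53030283 to 53160032). Trem2, a lipid-sensing myeloid receptor, rose from 290.3 ± 43.1 to 895 ± 137 FPKM (log2 1.62 ± 0.17; adjusted p = 8.45e-04; chromosome 17, 48346334 to 48354251). On the list of cholesterol efflux and LXR targets, 8 of 14 tested members were higher and 1 was lower (9 and 1 adjusted over the list alone), with a camera adjusted p of 4.18e-04. That call had an adjusted p of 0.346 with an estimated correlation. Mylip, which marks the LDL receptor for breakdown, rose from 32.2 ± 5.3585 to 88.9 ± 1.81 FPKM, and the desaturase Scd1 fell from 15.3 ± 4.15 to 4.71 ± 0.395 FPKM. The phospholipid carrier Pltp rose from 24.9 ± 4.603 to 73.01 ± 4.99 FPKM, with an authors' q-value of 0.0806. On the list of lipid uptake and scavenger receptors, 8 of 16 were higher and 3 were lower, the same counts adjusted over the list alone. Camera gave an adjusted p of 0.0421, and an adjusted p of 0.346 with an estimated correlation. Clec7a, a receptor for fungal glucans, rose on this list from 58.535 ± 11.1 to 409 ± 41.5 FPKM, and the haemoglobin receptor Cd163 fell from 21.6 ± 3.92 to 7.32 ± 0.951 FPKM. The uptake list's camera adjusted p was 0.104 without 3-day replicate 2, 0.0528 without 7-day replicate 1, 0.211 with quantile normalization and 0.0691 with genes at 1 FPKM or more. Apoe was set aside, because it is listed at 0 in all 3 libraries at 7 days beside a mean of 5849 FPKM at 3 days. Nr1h3, the gene of LXR alpha, has no row in the table analysed.

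Lipid droplet and lipolysis genes rose in 11 of 16 tested members and fell in 1, the same counts adjusted over the list alone. The camera adjusted p was 2e-04, and the adjusted p was 0.346 with an estimated correlation. Lipa, the lysosomal acid lipase, rose from 233 ± 33.04 to 561 ± 35.2 FPKM (log2 1.27 ± 0.14). Mgll, which splits monoglycerides, rose from 1.45 ± 0.787 to 6.54 ± 1.23 FPKM (log2 1.67 ± 0.27), and the phospholipase Pla2g7 from 398 ± 86.96 to 877 ± 58.2 FPKM (log2 1.16 ± 0.18). Of the lipid droplet genes, 0 were lower without 7-day replicate 2 or with quantile normalization. Of the genes of fatty acid beta-oxidation, 14 of 21 were higher and 0 were lower (15 and 0 adjusted over the list alone). The camera adjusted p was 3.01e-05, with an adjusted p of 0.346 with an estimated correlation. The subunits of the mitochondrial trifunctional protein, Hadhb and Hadha, rose from 26.4 ± 6.77 to 63.7 ± 8.04 FPKM and from 62.1 ± 3.07 to 112 ± 3.89 FPKM. The dehydrogenase Acadm rose from 31.2 ± 3.46 to 58.9 ± 0.931 FPKM and the thioesterase Acot2 from 3.47 ± 0.267 to 9.79 ± 0.718 FPKM. Of the beta-oxidation genes, 8 were higher without 7-day replicate 2 and 9 without 7-day replicate 3. Cholesterol synthesis genes were called lower in 5 of 20 and higher in 0 (4 and 0 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.169; 0.606 with an estimated correlation). Sqle, the squalene epoxidase, fell from 25.2 ± 0.873 to 11.2 ± 1.33 FPKM and Pmvk from 12.2 ± 1.0325 to 7.76 ± 0.506 FPKM. Fdft1, the squalene synthase, fell from 10.7 ± 2.55 to 6.796 ± 0.815 FPKM, and lost its call with quantile normalization, with the replicate number as a block and without any single library but 3-day replicate 1 (adjusted p up to 0.122). Of the cholesterol synthesis genes, 2 were higher without 3-day replicate 2; 3 were lower without 3-day replicates 2 or 3 or 7-day replicates 1 or 2. Among nuclear receptors and their partners, 4 of 10 were higher and 2 lower (4 and 3 adjusted over the list alone); the camera adjusted p was 0.672, and 0.766 with an estimated correlation. Pparg, a receptor for fatty acid ligands, rose from 4.26 ± 0.694 to 11.99 ± 0.567 FPKM (log2 1.31 ± 0.14, SE; adjusted p = 8.79e-04; chromosome 6, 115360790 to 115490448). That list's median log2 change was -0.07 and its mean 0.07. Its retinoid receptors Rxrb and Rxra rose from 4.805 ± 0.0746 to 8.8999 ± 0.81145 FPKM and from 20.6 ± 4.49 to 33.7 ± 3.002 FPKM; the authors' q-value of Rxrb was 0.18, and Rxra had an adjusted p of 0.0579 without 7-day replicate 3. Vdr, the vitamin D receptor, fell from 1.65 ± 0.913 to 0.332 ± 0.141 FPKM, and lost its call with quantile normalization (adjusted p = 0.251), with the replicate number as a block and without any single library but 3-day replicate 3. Of the nuclear receptors and partners, 2 were higher without 7-day replicate 3; 0 were lower without any 7-day library or with quantile normalization and 1 without any 3-day library. In the same libraries, the 10 tested macrophage markers had a median log2 change of 0.57, beside 0.72 for efflux, 0.36 for uptake, 0.82 for lipid droplet and 0.49 for beta-oxidation genes.

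**Figure D2:**
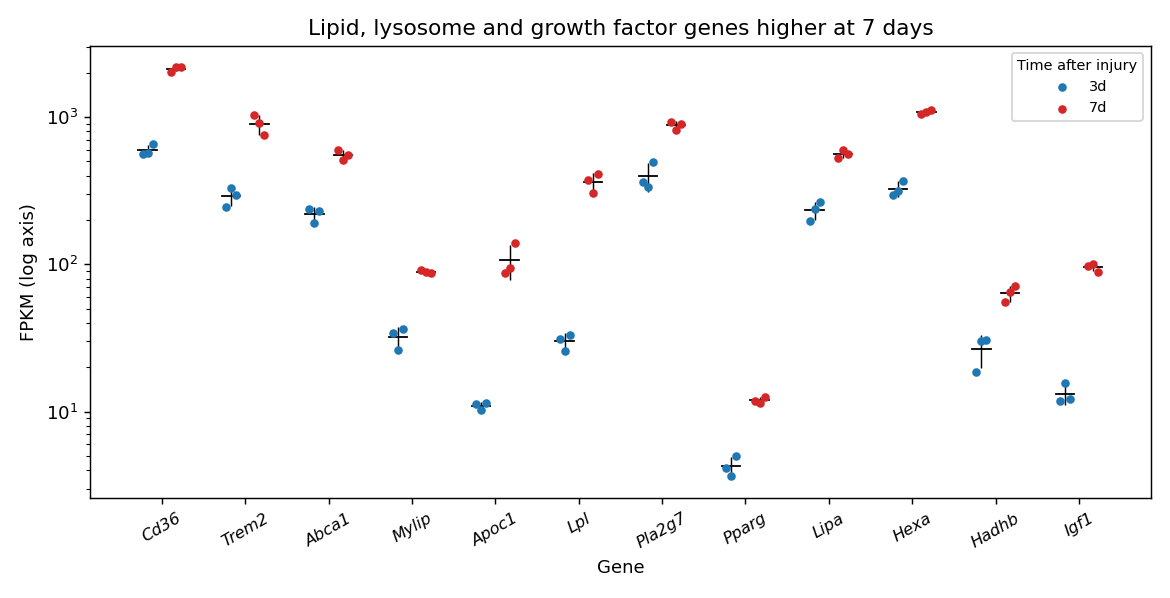
FPKM on a log axis of 12 named genes in each library at 3 days (blue) and 7 days (red); horizontal lines are group means and vertical lines 1 SD (n = 3). Every 7-day value lies above every 3-day value of its gene, with Cd36 the most abundant at 7 days (2121 FPKM).

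Lysosomal genes formed the list with the lowest camera p among those that were higher. Of 27 tested members, 20 were higher and 1 was lower (22 and 1 adjusted over the list alone), with a median log2 change of 0.81 and a camera adjusted p of 5.24e-09. With an estimated correlation this had an adjusted p of 0.346. Hexa, which takes part in the breakdown of gangliosides, rose from 326 ± 39.435 to 1076 ± 32.8 FPKM (log2 1.73 ± 0.14). Glb1, the lysosomal beta-galactosidase, rose from 34.9 ± 6.17 to 96.2 ± 2.07 FPKM, and Scarb2, a lysosomal membrane protein, from 129.5 ± 10.1 to 366 ± 22.2 FPKM. The member that fell was the collagen-degrading cathepsin Ctsk, from 44.3 ± 9.25 to 23.3 ± 5.81 FPKM, named after its value was seen. The abundant members Ctsb, Ctsd, Ctss, Psap and Gpnmb are listed at 0 in all 7-day libraries and were not tested. Macrophage markers had a median log2 change of 0.57 in these libraries.

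Genes of phagocytosis and apoptotic cell clearance were higher in 9 of 19 tested members and lower in 4, the same counts adjusted over the list alone. The list passed camera (adjusted p = 0.0255; adjusted p = 0.346 with an estimated correlation). Tyrobp, the signalling adaptor of Trem2, rose from 242 ± 61.1 to 896 ± 167 FPKM (log2 1.90 ± 0.23). Tyro3, a receptor for dying cells, fell from 10.1 ± 2.95 to 3.39 ± 0.668 FPKM (log2 -1.32 ± 0.23). Of the phagocytosis genes, 2 were lower without 7-day replicate 1. This list's camera adjusted p was 0.21 with quantile normalization and 0.0526 with genes at 1 FPKM or more. Of the complement genes, 6 of 12 were higher and 2 were lower (6 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.2; 0.762 with an estimated correlation). C1qb and C1qc, chains of the first complement component, rose from 216 ± 27.6 to 486 ± 17.3 FPKM and from 292 ± 58.8 to 726 ± 91.4 FPKM. Itgax, an integrin chain of complement receptors, rose from 12.1 ± 0.931 to 36.875 ± 4.28 FPKM, and Cd55, which dismantles complement convertases, fell from 4.2925 ± 1.53 to 1.0685 ± 0.244 FPKM. Antigen presentation genes were higher in 8 of 12 and lower in 0, the same counts adjusted over the list alone, with a camera adjusted p of 0.00448 and an adjusted p of 0.346 with an estimated correlation. With quantile normalization the adjusted p was 0.0733. The class I genes H2-D1 and H2-K1 rose from 591 ± 119 to 1247.5 ± 51.5 FPKM and from 446 ± 80.205 to 895 ± 39.2 FPKM. The class II chaperone gene H2-DMb1 rose from 12.3 ± 2.03 to 26.2 ± 2.19 FPKM. B2m, the light chain of class I, rose from 1838 ± 647 to 4207 ± 914 FPKM, and lost its call with quantile normalization (adjusted p = 0.135) and without 3-day replicates 1 or 2 or 7-day replicates 2 or 3 (adjusted p from 0.0648 to 0.0812). Of the antigen presentation genes, 3 were higher without 3-day replicate 2 or with quantile normalization, 4 without 3-day replicate 1 or 7-day replicate 2 and 5 without 3-day replicate 3. H2 genes share sequence, so reads may be split between them and their values are uncertain. The 10 macrophage markers had a median log2 change of 0.57, beside 0.43 for phagocytosis, 0.30 for complement and 0.71 for antigen presentation. Of these markers, Mertk, Cd14, Fcgr1 and Tyrobp are also on the phagocytosis list, and C1qa and Itgam on the complement list. For those lists they are therefore not a separate measure.

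Interferon response genes were lower at 7 days in 19 of 20 tested members and higher in 0, with the same counts adjusted over the list alone. The median log2 change was -1.27 and the camera adjusted p 1.28e-09 (adjusted p = 0.346 with an estimated correlation). Isg15, a ubiquitin-like protein attached to others during infection, fell from 50.8 ± 7.79 to 6.87 ± 1.31 FPKM (log2 -2.72 ± 0.16, SE; adjusted p = 1.32e-04). Irf7, the transcription factor that drives type I interferon genes, fell from 93.6 ± 17.6 to 16.2 ± 1.91 FPKM (log2 -2.45 ± 0.16). The antiviral gene Oasl1 fell from 23.6 ± 4.301 to 5.13 ± 1.397 FPKM (log2 -2.01 ± 0.20). Irf1 was the member not called (11.2 to 11.4 FPKM), named after its value was seen. Markers of other cells were lower in the same libraries: summed oligodendrocyte markers were 340.4, 697 and 432 FPKM at 3 days and 158, 146 and 174 FPKM at 7 days. Inflammatory monocyte markers summed to 665, 657 and 772 FPKM at 3 days and 289.6, 304 and 334 FPKM at 7 days.

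Chemokines and their receptors were lower in 15 of 25 tested members and higher in 4 (16 and 4 adjusted over the list alone). Its camera adjusted p was 0.00298 (adjusted p = 0.346 with an estimated correlation). The monocyte attractant Ccl2 fell from 196 ± 69.3 to 26.7 ± 6.67 FPKM (log2 -2.80 ± 0.26). Its relatives Ccl7 and Ccl12 fell from 135 ± 36.4 to 19.9 ± 5.54 FPKM and from 94.97 ± 38.3 to 12.7 ± 0.728 FPKM. These neighbouring genes are similar in sequence, so the split of reads between them is uncertain. Cx3cr1, the fractalkine receptor, rose from 17.4 ± 2.299 to 72.8 ± 7.05 FPKM on the same list. Pro-inflammatory activation genes were lower in 8 of 18 and higher in 2 (9 and 3 adjusted over the list alone). The camera adjusted p was 0.0233 (adjusted p = 0.346 with an estimated correlation), and the Fisher exact test of the lower members gave an adjusted p of 0.0536. Socs3, which dampens cytokine signalling, fell from 18.2 ± 2.97 to 3.99 ± 0.785 FPKM and the formyl peptide receptor Fpr2 from 7.04 ± 0.967 to 1.47 ± 0.393 FPKM. The cytokine gene Il1a rose from 7.88 ± 1.44 to 23.545 ± 0.334 FPKM. Ptgs2, a cyclooxygenase, fell from 3.71 ± 2.14 to 0.623 ± 0.392 FPKM, with an adjusted p of 0.0505 without 7-day replicate 2. Alternative activation genes were lower in 8 of 14 and higher in 3 (10 and 3 adjusted over the list alone). The camera adjusted p was 0.0421 (adjusted p = 0.346 with an estimated correlation). Arg1, which breaks down arginine, fell from 510.3 ± 103 to 67.2 ± 3.09 FPKM (log2 -2.89 ± 0.15). The chitinase-like Chi3l3, which has close relatives and is uncertain, fell from 224 ± 38.1 to 78.7 ± 16.915 FPKM. Igf1, the insulin-like growth factor, went the other way, from 13.2 ± 2.11 to 96.005 ± 6.23 FPKM (log2 2.78 ± 0.13). The alternative activation list's camera adjusted p was 0.0777 without 3-day replicate 1, 0.0807 without 3-day replicate 3, 0.0633 without 7-day replicate 1 and 0.0565 after centring on the median gene. Of the alternative activation genes, 5 were lower without 3-day replicate 3 or 7-day replicates 1 or 3. Inflammatory monocyte markers, with a median log2 change of -1.02, and oligodendrocyte markers, with -1.40, were lower in the same libraries as these lists.

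Iron and heme handling genes were lower in 7 of 12 tested members and higher in 0 (7 lower and 1 higher adjusted over the list alone). The list passed camera (adjusted p = 0.0224; adjusted p = 0.346 with an estimated correlation). Hmox1, which opens the heme ring, fell from 1221 ± 206 to 267 ± 60.475 FPKM (log2 -2.20 ± 0.21, SE; adjusted p = 6.60e-04). The ferritin heavy chain gene Fth1 fell from 3129.6 ± 534 to 829 ± 130.3 FPKM (log2 -1.91 ± 0.21). Lcn2, which binds bacterial iron carriers and is also a neutrophil marker, fell from 3.83 ± 1.51 to 0.378 ± 0.07199 FPKM. Of the iron and heme genes, 1 was higher without 3-day replicate 1. Red cell markers summed to 164, 179 and 213 FPKM at 3 days and 16.4, 22.4 and 15.9 FPKM at 7 days. Matrix proteases and inhibitors held 11 lower and 5 higher members of 19 (12 and 6 adjusted over the list alone). The one-sided Fisher exact test of the lower members gave an adjusted p of 0.00289, and camera an adjusted p of 0.149 (0.632 with an estimated correlation). Besides Mmp12, which rose, the protease inhibitor Timp1 fell from 35.9 ± 14.3 to 5.78 ± 1.91 FPKM. The matrix protein genes Thbs1 and Fn1 fell from 975 ± 198 to 196 ± 5.72 FPKM and from 580.0 ± 101 to 122 ± 20.5 FPKM. Fibroblast and pericyte markers summed to 131, 315 and 179 FPKM at 3 days and 124, 125 and 223 FPKM at 7 days. Growth factors and repair cytokines held 4 higher and 4 lower members of 17, the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.851; 0.875 with an estimated correlation). Apart from Igf1, the named member Hbegf fell from 5.11 ± 1.66 to 1.03 ± 0.165 FPKM. Lif fell from 1.7665 ± 1.07 to 0.0532 ± 0.0921 FPKM, with an authors' q-value of 0.374 and an adjusted p of 0.0549 with quantile normalization. Of the growth factors and cytokines, 2 were higher without 3-day replicate 2 or 7-day replicates 2 or 3.

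**Figure D3:**
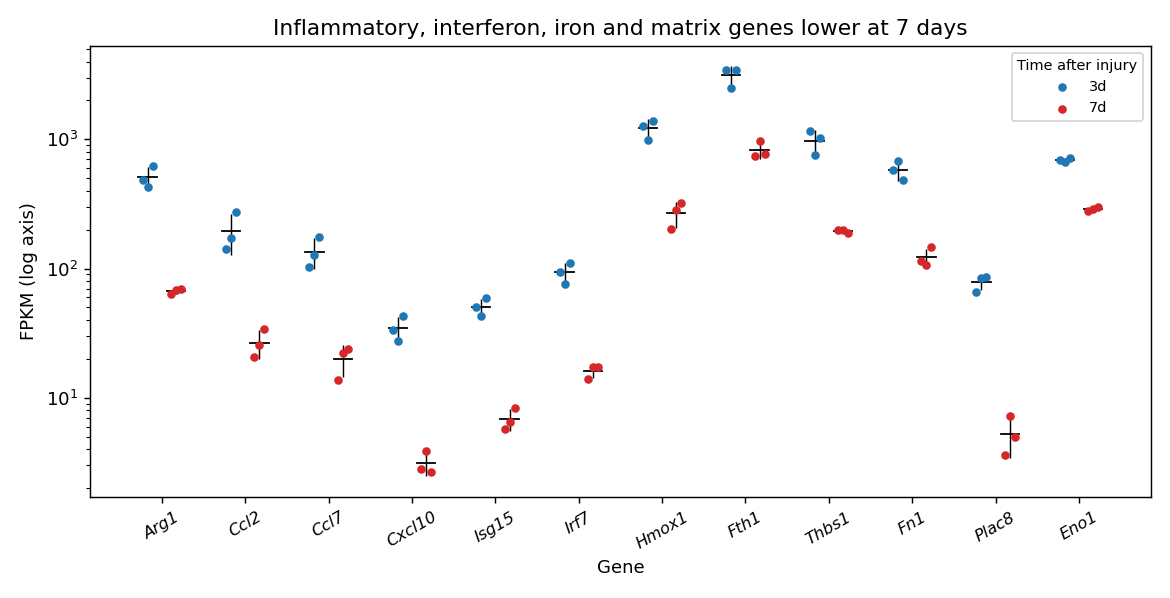
FPKM on a log axis of 12 named genes in each library at 3 days (blue) and 7 days (red); horizontal lines are group means and vertical lines 1 SD (n = 3). Every 7-day value lies below every 3-day value of its gene, from Fth1 (829 FPKM at 7 days) to Cxcl10 (3.11 FPKM).

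Glycolysis and hypoxia response genes were lower in 11 of 21 tested members and higher in 1, the same counts adjusted over the list alone. Its camera adjusted p was 0.00211 (adjusted p = 0.346 with an estimated correlation). Eno1, the enolase of glycolysis, fell from 692 ± 26.6 to 291 ± 10.6 FPKM (log2 -1.25 ± 0.11). The phosphofructokinase Pfkp fell from 81.7 ± 3.45 to 44.6 ± 2.33 FPKM (log2 -0.86 ± 0.089) and the lactate carrier Slc16a3 from 24.5 ± 2.42 to 13.5 ± 0.727 FPKM (log2 -0.81 ± 0.11). The member that rose was Pdk1, which inhibits pyruvate dehydrogenase (15.01 ± 1.34 to 19.4 ± 1.404 FPKM), named after its value was seen. Adm, a hypoxia-induced peptide hormone gene, fell from 1.86 ± 0.617 to 0.248 ± 0.13165 FPKM. Of the glycolysis and hypoxia genes, 0 were higher without any 1 of the 6 libraries or with quantile normalization; 6 were lower without 3-day replicate 3 or 7-day replicate 3 and 7 without 7-day replicate 1. Neuron markers, with a median log2 change of -1.49, were lower in the same libraries, beside -0.34 for this list. Oxidative phosphorylation genes were higher in 7 of 27 and lower in 3, the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.263; 0.809 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, rose from 157 ± 10.6 to 242 ± 19.765 FPKM. Another subunit, Sdhb, rose from 84.7 ± 12.3 to 128 ± 13.1 FPKM, with an adjusted p of 0.075 with quantile normalization and 0.0517 without 7-day replicate 2. Of complex I, Ndufa1 rose from 53.2 ± 11.4 to 91.9 ± 28.115 FPKM and Ndufab1 fell from 72.1 ± 7.66 to 46.9 ± 7.84 FPKM. Ndufab1 had an adjusted p of 0.0513 without 7-day replicate 3, and Ndufa1 lost its call after centring, with quantile normalization and without any of 4 single libraries (adjusted p from 0.0529 to 0.121). Of the oxidative phosphorylation genes, 1 was higher with quantile normalization, 2 without 7-day replicate 2 and 3 without 7-day replicate 3; 1 was lower without 3-day replicate 3 or 7-day replicate 3. Cell cycle genes were higher in 1 of 29 and lower in 1 (1 and 0 adjusted over the list alone), with a camera adjusted p of 0.932 and 0.97 with an estimated correlation. Pcna, the sliding clamp of replication, rose from 106 ± 9.2615 to 153 ± 8.12 FPKM. The other called member, Mcm7 (20.7 ± 1.22 to 16.2 ± 0.195 FPKM), lost its call without any single library but 3-day replicate 3, with adjusted p from 0.0517 to 0.0906, and with the replicate number as a block (0.0508); its authors' q-value was 0.264. Of the cell cycle genes, 2 were higher without 3-day replicate 2; 0 were lower without 3-day replicate 2 or 7-day replicates 2 or 3 and 2 with quantile normalization. Ribosomal protein genes were higher in 1 of 29 and lower in 3 (0 and 0 adjusted over the list alone), with a camera adjusted p of 0.277 and 0.835 with an estimated correlation. Rpl5 rose from 506 ± 23.7 to 758 ± 122 FPKM, and Rpl13, Rplp1 and Rps6 fell from 109 ± 9.5145 to 82.7 ± 2.04 FPKM, from 415 ± 40.3 to 287 ± 32.1 FPKM and from 53.5 ± 0.512 to 44.335 ± 0.403 FPKM. Each of the 4 lost its call without some single libraries, with adjusted p up to 0.0713 for Rpl5, 0.0671 for Rpl13, 0.0692 for Rplp1 and 0.0992 for Rps6. With quantile normalization Rpl5 had an adjusted p of 0.16, and Rps6 had an authors' q-value of 0.127 and an adjusted p of 0.0537 with the replicate number as a block. Of the ribosomal protein genes, 0 were higher without any 3-day library or 7-day replicates 1 or 3 or with quantile normalization; 0 were lower without 3-day replicate 3 or 7-day replicates 1 or 2, 1 without 7-day replicate 3, 8 without 3-day replicate 1 and 12 with quantile normalization. Rpl22, the tagged protein's own gene, measured 47.2 ± 6.13 FPKM at 3 days and 45.3 ± 4.94 FPKM at 7 days and was not called (log2 -0.06 ± 0.13; adjusted p = 0.739). The RNA measured does not tell tagged from untagged Rpl22.

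Markers of myeloid cells moved in different directions. Macrophage markers were higher in 6 of 10 tested members and lower in 2 (7 and 2 adjusted over the list alone). The camera adjusted p was 0.0224 (adjusted p = 0.346 with an estimated correlation). Mertk, a receptor for dying cells, rose from 42.6 ± 2.999 to 77.4 ± 3.87 FPKM, and the endotoxin co-receptor Cd14 fell from 27.2 ± 3.37 to 14.5 ± 1.2915 FPKM. The macrophage call had an adjusted p of 0.191 with quantile normalization and 0.0697 in the authors' filtered table. C1qa, the third chain of the first complement component, rose on this list from 503 ± 111 to 967 ± 107 FPKM. Of the macrophage markers, 1 was lower without 7-day replicate 1. Inflammatory monocyte markers were lower in 7 of 11 and higher in 1, the same counts adjusted over the list alone. Camera gave an adjusted p of 0.00211, and an adjusted p of 0.346 with an estimated correlation. Vcan fell from 25.2 ± 5.13 to 4.59 ± 1.01 FPKM and Ms4a4c from 137 ± 27.355 to 30.6 ± 4.92 FPKM. Chi3l3 and Hp of this list also stand on the alternative activation and iron lists. Markers that in the healthy cord mark microglia were higher in 6 of 8 and lower in 1 (6 and 2 adjusted over the list alone). The list passed camera (adjusted p = 0.0185; adjusted p = 0.346 with an estimated correlation). Besides Cx3cr1, the purine receptor P2ry13 (7.51 ± 2.91 to 20.9 ± 2.59 FPKM) and Fcrls (41.9 ± 7.44 to 104 ± 6.72 FPKM) rose. Sparc fell from 91.5 ± 42.3 to 40.6 ± 8.97 FPKM, and lost its call without 3-day replicate 3 or 7-day replicates 1 or 2 (adjusted p from 0.0595 to 0.0885). Of the microglia markers, 0 were lower without 3-day replicate 3 or 7-day replicates 1 or 2 and 2 without 3-day replicate 1. Neutrophil markers were lower in 5 of 12 and higher in 2 (7 and 2 adjusted over the list alone). The list did not pass camera (adjusted p = 0.0779; 0.346 with an estimated correlation). Mmp9 fell from 16.2 ± 6.705 to 3.59 ± 1.58 FPKM and S100a9 from 20.1 ± 3.88 to 7.69 ± 2.99 FPKM. Prtn3 fell from 1.48 ± 0.214 to 0.412 ± 0.20095 FPKM, with an adjusted p of 0.308 with quantile normalization. Of the neutrophil markers, 1 was higher without any 3-day library or 7-day replicates 1 or 2 or with quantile normalization; 3 were lower with quantile normalization. Dendritic cell markers held 2 higher and 1 lower of 5, T and NK cell markers 2 higher and 1 lower of 7 and B cell markers 1 higher and 1 lower of 3. Adjusted over the list alone, these were 2 and 1, 2 and 2, and 1 and 1. Their camera adjusted p was 0.672, 0.869 and 0.672, and 0.809, 0.875 and 0.766 with an estimated correlation. The dendritic cell list had a median log2 change of -0.34 and a mean of 0.20, and the T and NK cell list a median of -0.16 against a camera direction of up. Il7r rose from 60.4 ± 5.79 to 102 ± 5.4075 FPKM and Thy1, which neurons also carry, fell from 7.46 ± 4.01 to 1.81 ± 0.137 FPKM. Cd4 rose from 0.231 ± 0.127 to 1.5725 ± 0.362 FPKM and Cd79b from 0.923 ± 0.356 to 3.104 ± 0.336 FPKM. Batf3 rose from 2.2285 ± 0.683 to 5.61 ± 2.21 FPKM, with an authors' q-value of 0.37, and lost its call without any single library but 7-day replicate 2 (adjusted p from 0.0545 to 0.0864). Ebf1 fell from 3.51 ± 1.17 to 1.06 ± 0.372 FPKM, with an adjusted p of 0.0778 with quantile normalization. Of the dendritic cell markers, 1 was higher without any 3-day library or 7-day replicates 1 or 3; 0 were lower without 3-day replicates 2 or 3 or 7-day replicates 2 or 3 or with quantile normalization. Of the T and NK cell markers, 2 were lower without 3-day replicate 1. Of the B cell markers, 2 were higher with quantile normalization; 0 were lower with quantile normalization.

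Markers of oligodendrocytes, neurons, astrocytes, red cells and endothelial cells were lower at 7 days. Oligodendrocyte markers were lower in 13 of 13 tested members (13 adjusted over the list alone). Camera gave an adjusted p of 2e-05, and an adjusted p of 0.346 with an estimated correlation. The myelin genes Mog and Mobp fell from 32.6 ± 11.5 to 5.56 ± 1.38 FPKM and from 139 ± 27.1 to 48.3 ± 7.91 FPKM. Ugt8a fell from 23.8 ± 13.8 to 5.43 ± 0.602 FPKM and Cldn11 from 20.96 ± 8.97 to 5.2465 ± 1.301 FPKM. Neuron markers were lower in 13 of 14 (13 adjusted over the list alone). Its camera adjusted p was 2.5e-05 (adjusted p = 0.346 with an estimated correlation). Uchl1 fell from 60.9 ± 25.5 to 6.55 ± 1.14 FPKM and Stmn2 from 26.325 ± 11.6 to 3.99 ± 0.0669 FPKM. Tubb3 fell from 13.6 ± 9.12 to 2.16 ± 0.134 FPKM. Of the neuron markers, 8 were lower without 7-day replicates 2 or 3. Astrocyte markers were lower in 6 of 10 and higher in 0 (8 and 0 adjusted over the list alone). The camera adjusted p was 0.00491 (adjusted p = 0.504 with an estimated correlation). The glutamate transporter gene Slc1a2 fell from 35.5 ± 11.2 to 11.1 ± 1.29 FPKM. Sox9 fell from 2.8455 ± 1.03 to 0.50725 ± 0.0962 FPKM and Gja1 from 23.9 ± 10.3 to 7.23 ± 1.62 FPKM. Gfap fell from 223 ± 147 to 68.6 ± 8.81 FPKM, and lost its call without 3-day replicate 3 or any 7-day library (adjusted p from 0.0524 to 0.0791). Of the astrocyte markers, 3 were lower without 7-day replicates 1 or 2. Erythroid markers were lower in 4 of 5 and higher in 0, the same counts adjusted over the list alone. Camera gave an adjusted p of 6.72e-04, and an adjusted p of 0.346 with an estimated correlation. Hbb-b1 fell from 13.8 ± 7.06 to 1.699 ± 0.564 FPKM and Alas2, the heme synthesis enzyme of red cells, from 3.0004 ± 0.62625 to 0.438 ± 0.0784 FPKM. Hba-a1, a near-identical copy of Hba-a2 and as uncertain, fell from 33.6 ± 5.0345 to 3.36 ± 0.325 FPKM. Endothelial markers were lower in 6 of 8 and higher in 1 (7 and 1 adjusted over the list alone). The list passed camera (adjusted p = 0.00683; adjusted p = 0.346 with an estimated correlation). Tek fell from 7.1095 ± 1.32 to 0.573 ± 0.030395 FPKM, and Flt1, which macrophages can also express, rose from 3.36 ± 0.928 to 12.355 ± 1.84 FPKM. Esam fell from 6.57 ± 3.17 to 0.604 ± 0.0352 FPKM and Cdh5 from 14.3 ± 8.05 to 3.597 ± 0.629 FPKM. The endothelial median log2 change was -1.46, but 0.05 among the members in the authors' filtered table. Fibroblast and pericyte markers were lower in 4 of 8 (5 lower and 1 higher adjusted over the list alone) and Schwann cell markers in 3 of 6 (3 adjusted over the list alone). These lists did not pass camera, with adjusted p of 0.2 and 0.0569, and 0.762 and 0.558 with an estimated correlation. Cdh19 fell from 5.18 ± 1.13 to 0.972 ± 0.0915 FPKM. Sox10 fell from 2.79 ± 1.61 to 0.57585 ± 0.187 FPKM, and lost its call with quantile normalization (adjusted p = 0.101) and without 7-day replicates 1 or 2 (0.0626 and 0.0636). Of the fibroblast and pericyte markers, Dcn fell from 35.97 ± 24.98 to 9.86 ± 2.15 FPKM, Pdgfra from 5.301 ± 2.5975 to 1.82 ± 0.524 FPKM, Rgs5 from 7.097 ± 3.5995 to 2.6505 ± 0.836 FPKM and Pdgfrb from 4.66 ± 1.79 to 2.17 ± 0.187 FPKM. All 4 lost their calls without some single libraries, with adjusted p up to 0.0825, 0.074, 0.0965 and 0.097. With quantile normalization, Pdgfra, Rgs5 and Pdgfrb had adjusted p of 0.0767, 0.0712 and 0.158. Of the fibroblast and pericyte markers, 1 was higher with quantile normalization; 0 were lower without 7-day replicates 1 or 2, 1 without 3-day replicate 3 and 2 without 3-day replicate 2 or with quantile normalization. Of the Schwann cell markers, 1 was lower without 7-day replicate 1 or with quantile normalization. Among the libraries at 3 days, replicate 2 had the highest sums of oligodendrocyte (697 FPKM), astrocyte (622 FPKM) and neuron markers (545 FPKM). Without it, 2085 genes were higher and 2307 lower.

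**Figure D4:**
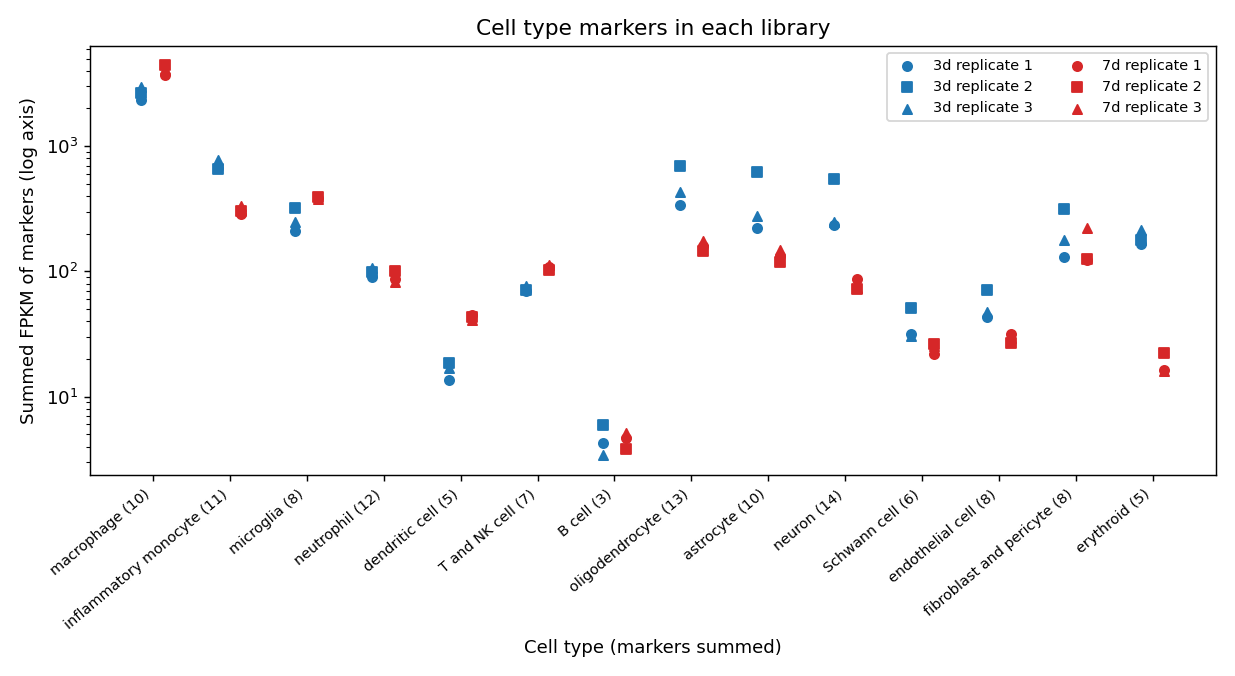
Summed FPKM, on a log axis, of the tested markers of each cell type in each of the 6 libraries at 3 days (blue) and 7 days (red), with marker shapes for replicates and the number of markers in brackets. Erythroid markers lie between 164 and 213 FPKM at 3 days and between 15.9 and 22.4 FPKM at 7 days, and macrophage markers between 2351 and 2983 FPKM and between 3718 and 4408 FPKM.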

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

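Of the tests in this part, the comparisons of marker lists with each other, the test of failed estimates and the test of dilution were chosen only after the results were seen, and quantile normalization was added after the data were seen.

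The real split of the 6 libraries called 5098 genes with limma, and the highest of the other 9 splits into 3 and 3 called 0 (270 at an unadjusted p under 0.05, against 6517 in the real split). Only 1 of the 10 splits, the real split, called as many, and 10 splits are too few for a share under 0.05. Each of the other 9 splits also puts 3-day and 7-day libraries in the same group. The difference between the times then widens the spread within their groups, so few or no calls are likely from the outset. These splits therefore do not show how many calls would be made without a change, and no conclusion is drawn from them.

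Some of the most abundant transcripts are listed at 0 in libraries of 1 time, which set their values outside the comparison. Apoe had a mean of 5849 FPKM at 3 days and is listed at 0 in all 7-day libraries. The same holds for the cathepsins Ctss (8462 FPKM at 3 days), Ctsd (5379 FPKM) and Ctsb (3221 FPKM), for Psap (3305 FPKM), and for Gpnmb (587 FPKM), whose deposited 7-day mean is 14.6 FPKM although its libraries are listed at 0. Lyz2 had a mean of 3760 FPKM at 3 days and was listed at 9435, 5862 and 0 FPKM at 7 days. The mitochondrial mt-Rnr1 is listed at 0 at 3 days and had a mean of 292 FPKM at 7 days. The authors' test status for Apoe, Ctsb, Ctsd, Ctss, Psap and mt-Rnr1 is not OK. A pair of fixed list members appear in the filtered table alone. Ifit3 went from 63.9 ± 10.9 FPKM at 3 days to 22.7 ± 3.61 FPKM at 7 days (log2 -1.45 ± 0.15, limma adjusted p = 4.11e-04). Itgb5 went from 53.2 ± 9.02 FPKM to 94.7 ± 9.68 FPKM (log2 0.83 ± 0.15, adjusted p = 0.00358).

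The lipid and lysosome lists were higher at 7 days, with 58 of 91 members higher, 6 lower and a median log2 change of 0.63; with an estimated correlation the camera adjusted p of each of the 5 lists was 0.346. Abundant transcripts that fail at 7 days could raise all other values there, but the median gene at 1 FPKM or more changed by 0.061, which argues against this as the cause. Less dilution by RNA of other cells would raise every transcript made by macrophages alone by 1 amount. The medians of the 91 list members and of 10 macrophage markers (0.57) differed by 0.06 (permutation p = 0.785 over genes, 95% bootstrap interval over genes -0.298 to 0.802). This neither shows that they are equal nor that they differ. Both values treat genes as independent and do not measure the spread between libraries. Of the 83 list members at a mean of 5 FPKM or more, however, 55 lay over 2 SE from their median (29 above and 26 below). So did 6 of the 10 macrophage markers (3 above and 3 below). This argues against 1 common rise as the whole cause if all are transcripts of macrophages alone. Members that other cells also express would rise less or fall, and which members these are was not tested. Dilution as a part of the cause stays open. A change in the cells with time after injury, such as uptake of myelin lipid, stays open as well and was not tested.

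Interferon response genes were lower at 7 days in 19 of 20 members, with a camera adjusted p of 0.346 with an estimated correlation. With quantile normalization 19 of these 19 were still called lower, which argues against the authors' scaling as the cause. Within the times, the median slope of these genes on a score of neural markers was -0.0064 (95% bootstrap interval over genes -0.219 to 0.05) with all 6 libraries. This lay below the 0.5 set as the bound for RNA of neural cells as the source. Such intervals treat genes as independent, although members of this list move together (estimated correlation 0.40), and are thus too narrow. Without 3-day replicate 2 the slope was 0.752 (0.681 to 0.969), but lysosome genes, which rose, then had a slope of 0.73, so what is left of the spread between libraries does not separate the sources and these cannot be told apart. A change with time in interferon signalling or in the mix of newly arrived and older macrophages stays open and was not tested.

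Markers of oligodendrocytes, astrocytes, neurons, endothelial cells and red cells were lower at 7 days (42 calls), although the precipitation should remove RNA of cells without LysM-Cre; at 3 days abundant ones were Gfap (223 FPKM), Mbp (176 FPKM) and Hba-a2 (135 FPKM). With an estimated correlation the camera adjusted p was 0.504 for astrocyte markers and 0.346 for each of the 4 other lists. With quantile normalization 35 of the 42 were still called lower, which argues against the authors' scaling as the whole cause. A smaller share of these cells would lower their markers alike, but the log2 ratios of 33 markers in these 5 lists differed between lists (Kruskal-Wallis permutation p = 8e-04), with medians of -3.32 in 3 erythroid, -2.06 in 10 neuron, -1.77 in 9 oligodendrocyte, -1.49 in 8 astrocyte and -0.33 in 3 endothelial markers. The endothelial value is uncertain: its markers ranged from -1.99 to 1.88, macrophages can express Flt1 among them, and all 8 tested had a median fitted log2 change of -1.46. Without endothelial markers the 4 other lists still differed (30 markers, Kruskal-Wallis permutation p = 7.2e-04). The log2 ratios of 39 markers in 7 lists, with the fibroblast and Schwann cell markers that are not among the 42 calls, also differed (Kruskal-Wallis permutation p = 7e-05). Medians were then up to 3.31 apart, where the highest is the value of 1 Schwann cell marker. Oligodendrocyte, astrocyte and neuron markers also differed (27 markers, permutation p = 0.0099, medians up to 0.57 apart). These permutation tests treat each marker as independent. Markers of 1 list move together between libraries (estimated correlation 0.87 for oligodendrocyte, 0.79 for astrocyte and 0.74 for neuron markers). The p-values are thus too small, and whether 1 common share of neural RNA is the whole cause is not decided. Of these markers, the 3 erythroid ones (-3.41 to -3.02) fell more than every oligodendrocyte (lowest -2.55) and astrocyte marker (lowest -1.72), while neuron markers reached -4.57. A share that fell by another amount for each cell type, and a change with time in those cells or in what macrophages engulf, stay open and were not tested.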

How the results depend on the processing

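Alternatives added after the data were seen were quantile normalization, the rows with unmatched means, the authors' q-values, the estimated correlation, list results without each library, list medians and camera calls of single lists in the authors' filtered table, and the refits of named genes. At an adjusted p of 0.01 the counts were 1213 higher and 1196 lower, with a fitted log2 change of at least 1 as well 426 and 1347, and with that minimum on group means with a pseudocount of 1, 425 and 1380; these ask more of each gene by construction. With genes at 5 FPKM or more 1487 were lower, and 1433 with the authors' filtered table, where fewer genes were tested. Leaving out a library gave 1572 to 2207 higher and 1697 to 2565 lower, with fewer samples; the lowest of each came without 7-day replicate 2. Quantile normalization left 5 lists higher by camera in place of 9 and 6 enriched among higher genes in place of 10; the cause was not tested. The estimated correlation left 0 lists higher and 0 lower by camera. Correlated members were not the whole cause, since inflammatory monocyte markers had an estimated correlation of -0.0101, below the preset 0.01. Their unadjusted camera p still went from 5.94e-04 to 0.0227. What else raised it was not tested. Fry, which does not compare with other genes, called all 21. The endothelial median log2 change was 0.0521 in the authors' filtered table, which holds fewer of its members. For lists without a camera call, 23 comparisons moved the median by at least 1 SD between libraries of a time. Of these, 8 were with quantile normalization, 5 in the authors' filtered table and 4 with a pseudocount of 0.1. Another 3 were with genes at 1 FPKM or more, and 1 came without each 7-day library. Replicate numbers did not pair the libraries (residual r = 0.115, 0.0096 and 0.0105). The other 66 comparisons of counts of genes and of lists stayed within 1.5 times. Even so, quantile normalization gave 2317 higher and 1809 lower, and centring on the median gene 2020 and 2977, so the direction with more calls depends on the scaling. It also depends on the genes tested and on the block: 2509 were higher and 2423 lower at 1 FPKM or more, 2385 and 1487 at 5 FPKM or more, 2388 and 1433 in the authors' filtered table, and 2450 and 2425 with the replicate number as a block. Counts of called members within a list were less stable: 140 comparisons moved by over 1.5 times and 490 did not. Of the 140, 31 were at an adjusted p of 0.01, 16 with quantile normalization, 10 in the authors' filtered table, and between 10 and 16 on leaving out each library. With that filtered table, 3 oligodendrocyte, 7 neuron, 1 endothelial and 2 erythroid markers were lower, in place of 13, 13, 6 and 4. That table leaves out markers of each of these lists, such as Mog, Mobp, Stmn2, Tubb3, Tek, Cdh5, Hbb-b1 and Alas2. These counts thus fell at least in part because markers are absent, not because they stopped being lower. Of the 21 lists called by camera, 6 lost the call or turned under some alternative other than the estimated correlation. In turn, 12 comparisons gave a camera call to a list that had none. Of these, 4 were in the authors' filtered table, 2 with quantile normalization and 2 with genes at 1 FPKM or more. Another 2 came without 3-day replicate 1, 1 without 3-day replicate 3 and 1 with a pseudocount of 0.1. Of 132 named genes called, 29 lost the call somewhere and 0 reversed. Of the comparisons of named genes, 1984 were counted as the same, with direction and side of the threshold kept for called genes. A further 102 lost the threshold and 1, with quantile normalization, moved in value. Among the 1984, 133 compared only the log2 change of group means with a pseudocount of 1, which has no p-value. Relative depth, read from FPKM steps whose scaling is not stated, was 0.758 to 1 and limits what the lowest values can show. The number of reads is unknown.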

Other observations

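The gene lists in this part were chosen after the data were seen, and the Fisher exact tests are adjusted over the 7 added lists and both directions. These tests treat genes as independent, which members of a list need not be, and camera was not run on the added lists. Subunits of the vacuolar proton pump, which acidifies lysosomes, were higher at 7 days in 9 of 16 tested members and lower in 1 (one-sided Fisher exact adjusted p = 0.00645). Of these, 13 are on no fixed list, and 8 of the 13 were higher. All subunits but Atp6v1g2 reached a group mean of 5 FPKM or more, and the Fisher test was not matched on abundance. When only genes at 5 FPKM or more were tested, 2385 of 8606 were higher, against 2453 of all 13042. Atp6v1c1 rose from 103 ± 10.4 to 199 ± 7.71 FPKM (log2 0.95 ± 0.11) and Atp6v1e1 from 95.9 ± 8.04 to 156 ± 9.44 FPKM, and Atp6v0e2 fell from 5.64 ± 2.55 to 1.37 ± 0.115 FPKM. Macrophage markers had a median log2 change of 0.57 in the same libraries, and Atp6v0e2 was highest in 3-day replicate 2 (8.49 FPKM), the library with the highest neural marker sums.

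The other families did not pass the adjusted Fisher test in either direction. Toll-like receptors were higher in 4 of 10 and lower in 1 (adjusted p = 0.299 for higher). Tlr8, a receptor of RNA, rose from 43.5 ± 4.35 to 80.285 ± 0.9002 FPKM and Tlr4, the endotoxin receptor, from 25.7 ± 1.7997 to 43.7 ± 0.895 FPKM. Tlr5 fell from 2.38 ± 0.154 to 1.0775 ± 0.249 FPKM. Cd300 receptors, which bind lipids of dying cells, were higher in 3 of 7 (adjusted p = 0.299), with Cd300a rising from 14.8 ± 1.83 to 62.2 ± 3.5295 FPKM. Of the metallothioneins, 2 of 3 were lower (adjusted p = 0.299). Mt2 fell from 49.8 ± 20.998 to 9.17 ± 0.811 FPKM and Mt3 from 25.4 ± 12.2 to 2.302 ± 1.01 FPKM, both highest in 3-day replicate 2 (71.6 and 39.2 FPKM). Integrin subunits were higher in 5 of 20 and lower in 5 (adjusted p = 0.638 and 0.67), and membrane-spanning 4A genes were higher in 1 of 6 and lower in 3 (adjusted p = 0.299 for lower). Ms4a7 rose from 43.1 ± 11.505 to 150.2 ± 17.5 FPKM while Ms4a8a fell from 7.301 ± 1.8035 to 1.27 ± 0.431 FPKM.

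A shift of the macrophages towards a lipid-associated state, known from other tissues, is a candidate explanation of the lipid pattern. Of 34 genes described in such cells, 21 were higher and 3 lower (median log2 change 0.71, adjusted Fisher exact p = 5.48e-07), but 22 of them are on the fixed lists that prompted the question. Of 10 general macrophage markers, 6 were higher and 2 lower in the same libraries, with a median log2 change of 0.57. Tyrobp and Lgals3 are on both lists. Among the 12 on no fixed list, 5 were higher (Cst7, Cd9, Anxa5, Vat1 and Sgk1) and 0 lower, with a median log2 change of 0.44 and a one-sided Fisher exact p of 0.0577, which neither passes 0.05 nor counts against the hypothesis. Cd9 rose from 362 ± 31.7 to 636 ± 36.025 FPKM and Cst7 from 2.33 ± 0.253 to 5.87 ± 1.39 FPKM.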
